A study of Mus musculus with 6 samples.

How the data were processed

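RNA was sequenced from 6 samples of mouse bone marrow-derived cells, 3 from wild-type mice (WT 1 to WT 3) and 3 from mice lacking Txnip (KO 1 to KO 3), all 5 months old and of the C57BL/6 strain per the labels. Per the labels' protocols, marrow cells depleted of mature blood lineages were grown for 3 days with stem cell factor and thrombopoietin, and cells positive for CD41 were sorted before RNA extraction. The libraries followed standard Illumina protocols, whose read length and strand setting are not given in the sources used here.

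The deposited values are FPKM (fragments per kilobase of transcript, relative to the total of mapped fragments) per gene symbol and library, with 2 decimals. Per the submitters' processing notes, the authors used FastQC, Trimmomatic 0.39, STAR 2.7.0a and RSEM 1.2.31 with the mouse build mm9. The step each tool served, its settings and the gene annotation are not given in the sources used here. RSEM is a program that shares reads between similar transcripts by estimation, so values of close paralogs are estimates that depend on each other. The table held 24410 gene symbols, of which 7372 were listed at 0 in every library, and its 6 columns were all used.

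FPKM sums ranged from 715205 in KO 3 to 1131641 in WT 2. Rpph1 and Rmrp, short noncoding RNAs of RNase P and RNase MRP, took 30.4% of the WT 2 sum and between 10.7% and 20.6% of the others. Ribosomal protein genes took between 14.0% (KO 1) and 27.1% (KO 2). The files do not state depth. It was estimated from the spacing of low values of genes with a single RefSeq transcript, using GENCODE transcript lengths on GRCm38: 18200000 fragments in WT 1, 18600000 in WT 2, 17400000 in WT 3, 13200000 in KO 1 and 23600000 in KO 3. For KO 2 the best spacing, 9100000 fragments, stood out little from the next (a fit of 0.12 against 0.111), so its depth stays unknown. Because these lengths come from another build than mm9, the depths are approximate, and no interval or detection limit was computed from them. Among genes with a median of at least 20 FPKM, 10 were listed at 0 in at least 1 library. They include Txnip and the Y-linked Ddx3y and Eif2s3y, whose zeros follow genotype and sex, and several small noncoding RNAs. Amd1, an enzyme of polyamine synthesis, was at 85.3 FPKM in WT 1 and listed at 0 in WT 3 and KO 2, so a value of 0 can be a failed estimate.

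Groups came from the sample titles. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1), two-sided, KO against WT, on the 11249 genes with at least 1 FPKM in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. Gene lists were tested with camera from limma, at a preset correlation of 0.01 between genes, adjusted over the 34 of 35 lists with at least 4 measured members. Mitochondrially encoded transcripts, the remaining list, had 0 members in the table. Camera compares a list with all other tested genes, so its direction is relative to them. It was repeated with an estimated correlation, and fry was run beside it. Each list's median was also placed among 10000 random lists matched on mean expression. The lists covered megakaryocyte and platelet genes, markers of other blood cells, endothelium and stroma, metabolism, redox, stress, inflammation, cell cycle, apoptosis, autophagy, ribosomes, histones, proteasome, immediate early genes, sex-linked genes and neighbours of Txnip. The immediate early, cytosolic ribosomal protein, core histone and sex-linked lists were set as lists of sample quality. The tests, lists, alternatives and rule for named genes were set before the data were examined. In that rule, Txnip comes first. Up to 15 genes per direction follow, by size of change, if past the threshold, separated between the groups in all libraries and at 5 FPKM or more in the higher group. Where fewer than 5 pass, separated genes of smallest p fill up to 5 and are said not to pass. Each list adds its 4 members of smallest adjusted p. Predicted genes named only by number are skipped.

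The numbering of the replicates was checked before any fit with and without it was compared. Deviations from the group means correlated across genes between WT and KO libraries of the same number, with r of 0.81, 0.59 and 0.38 for numbers 1, 2 and 3. In both genotypes, libraries 1 and 2 held transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and library 3 held Xist instead. The numbers were therefore taken to pair the samples. The labels do not say what a number stands for, nor whether libraries of a genotype come from separate mice beyond the difference in sex. The p-values measure the spread between these samples, which may be partly technical. A fit with the number as a block was run beside the main one. "Pair" below means the KO and the WT library of the same number.

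The gene test was checked on 20 simulated data sets of 11249 genes built from the real means, replicate effects and a smoothed spread, with 200 genes changed. Noise was normal, with each gene's spread taken from the moderated residuals of the fit with the block and equal in all libraries. Shares recovered in the real data may therefore differ. For KO against WT, the test recovered 0.25% of 2-fold and 51.6% of 4-fold changes, with 0% of its calls wrong. With the block it recovered 81.4% and 95.9%, with 8.21% of its calls wrong, more than the threshold of 0.05 allows for. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.1, so none was used for single genes.

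The alternatives were another pseudocount, 2 other filters, 3 other scalings, other eBayes settings, array weights, the block, other thresholds, other list tests and each library left out in turn. Leaving out a library without the block unbalances the pairs, so those fits also take up differences between pairs. Combinations with the block, and a scaling without Rpph1 and Rmrp, were added after seeing the data. The reference at hand is GRCm38 and not mm9, so no coordinates are given; it served for chromosome, gene order and transcript length, with a chromosome found for 99.7% of tested genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the other tests and plots.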

Results

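Expression was profiled in CD41+ cells raised from the bone marrow of wild-type and Txnip knockout mice, 3 libraries of each. CD41, the integrin subunit encoded by Itga2b, marks the megakaryocyte lineage, and the question was what loss of Txnip changes during the development of megakaryocytes, the cells that make platelets. The sorted cells held megakaryocyte transcripts: Pf4, platelet factor 4, lay between 465 and 1545 FPKM and Itga2b between 83.2 and 152. Tubb1, the beta-tubulin of mature proplatelets, stayed between 0.17 and 1.47 FPKM. Genes of other myeloid cells were also abundant, with the granulocyte peroxidase Mpo between 782 and 1640 FPKM, the monocyte and granulocyte lysozyme Lyz2 between 522 and 1533, and the mast cell protease Cpa3 between 110 and 369. Apart from Cpa3, these genes were picked outside the naming rule to describe the cells. Depth, estimated for 5 of the libraries, ran from 13200000 fragments in KO 1 to 23600000 in KO 3. Libraries of the same number lay closest: Spearman correlations across tested genes were 0.983, 0.969 and 0.983 for pairs 1, 2 and 3 (genes are not independent replicates).

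**Figure D1:**
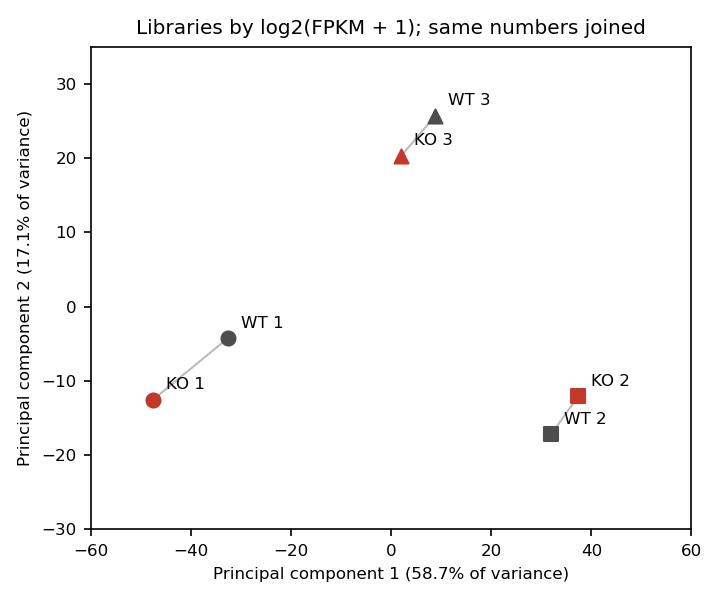
The 6 libraries by the first and second principal components of log2(FPKM + 1) over 11249 genes, holding 58.7% and 17.1% of the variance; grey libraries are WT, red are KO, and lines join the same replicate number. The first component places both libraries numbered 1 apart from both numbered 2, and on the components drawn each KO library lies beside the WT library of its number. The third component, not drawn, holds 12.5% of the variance and sets WT 2 (−23.9) and KO 2 (24.6) furthest apart.

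Txnip, which encodes the thioredoxin-interacting protein, an alpha-arrestin that binds thioredoxin and restrains glucose uptake, was at 112, 228 and 143 FPKM in WT 1 to WT 3. It was listed at 0 in KO 1 and KO 3 and at 0.04 in KO 2. The difference on the log2(FPKM + 1) scale was −7.26 (SE 0.28; limma, adjusted p = 2.02e-05), lower in 3 of 3 pairs, so the libraries match their genotype labels.

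Beyond Txnip, 1 gene passed the threshold. Cd1d2, a CD1d-type molecule that belongs to the family presenting lipids to T cells, was at 0.10, 0.25 and 0 FPKM in WT 1 to WT 3 and at 7.12, 9.10 and 7.24 in KO 1 to KO 3. Its difference was 2.98 (SE 0.25; limma, adjusted p = 0.00657), higher in 3 of 3 pairs. Cd1d2 is a close paralog of Cd1d1, so the share of reads between them is uncertain; Cd1d1 itself was 12.1 ± 2.48 FPKM in WT and 16.6 ± 3.23 in KO (SD, n = 3 each). Mnd1, a protein of meiotic recombination, was 18.6 ± 5.25 FPKM in WT and 48.8 ± 15.8 in KO (SD, n = 3 each). It differed by 1.33 and passed with the replicate number as a block but not without it (limma, adjusted p = 0.00752 and 1.00). Of the alternatives without the block, array weights alone also called it (limma, adjusted p = 0.00144). The estimation of those weights stopped before it converged, and that fit called 519 genes higher and 320 lower, so its results are weak evidence here and below. With the block the counts were 2 genes higher and 1 lower, against 1 and 1 without it. At an unadjusted p under 0.05, limma gave 46 genes higher and 30 lower, and 524 and 256 with the block. By chance a share of 0.05 of the 11249 tests would fall there. The fit without the block gave fewer than that and the fit with it more, so neither is a count of changed genes. The fit without the block leaves differences between pairs in its error, so genes it does not call may still differ. In 373 genes all KO libraries lay above all WT libraries and in 116 below, together 4.35% of those tested. Chance gives 10% for 3 against 3 exchangeable libraries, which these paired libraries are not, so the share cannot be read against it.

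The genes next in rank did not pass. Among those with higher values, the ectoenzyme Bst1 was 1.65 ± 0.45 FPKM in WT and 4.08 ± 0.91 in KO, the inducible heat shock protein gene Hspa1a 0.37 ± 0.31 and 1.92 ± 0.76, and the growth factor gene Mdk 0.33 ± 0.30 and 1.52 ± 0.28 (SD, n = 3 each). Among those with lower values, Fcer1a, the alpha chain of the IgE receptor of mast cells and basophils, was 28.9 ± 5.23 FPKM in WT and 13.8 ± 4.35 in KO (SD, n = 3 each). The annexin gene Anxa9 was 6.56 ± 1.72 and 2.01 ± 1.52, the adaptor gene Sh3d19 3.46 ± 0.58 and 0.64 ± 0.58, and the thioesterase gene Them4 2.93 ± 0.50 and 0.98 ± 0.23. Each of these 7 genes had its 3 KO libraries apart from its 3 WT libraries. Without WT 2, WT 3 or KO 3 the Cd1d2 call was lost (limma, adjusted p = 0.0660, 0.0827 and 0.1), while Txnip passed whichever library was left out.

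**Figure D2:**
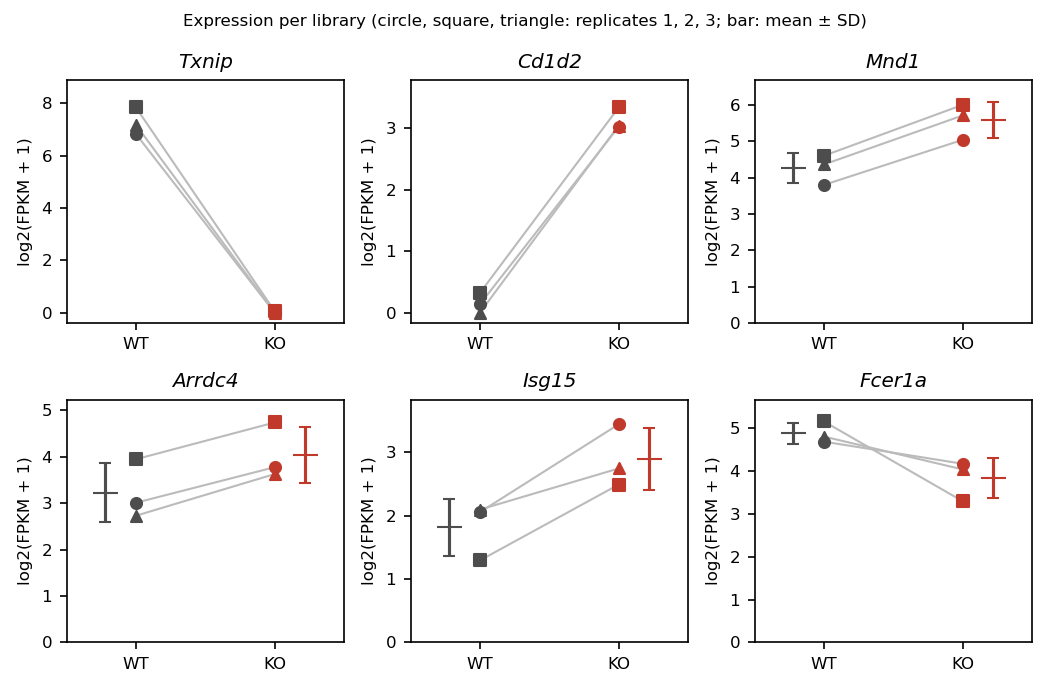
Expression of 6 genes in each library on the log2(FPKM + 1) scale; symbols mark replicate numbers, lines join WT and KO libraries of the same number, and bars give mean ± SD (n = 3) for genes with no value of 0. Txnip is lower and Cd1d2, Mnd1, Arrdc4 and Isg15 are higher in the KO library of each pair, and Fcer1a is lower; of these, Txnip and Cd1d2 pass the test without the block.

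Megakaryocyte and platelet genes did not pass as groups. Of 24 surface receptors 17 had higher and 7 lower values in KO, with a median change of 0.13 (camera, adjusted p = 0.406). Of 31 genes of granule cargo and formation, 22 were higher and 9 lower (median 0.11, adjusted p = 0.226). The 24 transcription factors split 13 to 11 (median 0.02, adjusted p = 0.922), the 36 proplatelet cytoskeleton genes 24 to 12 (median 0.06, adjusted p = 0.922) and the 42 integrin and platelet signalling genes 38 to 4 (median 0.12, adjusted p = 0.130). In 4 of these 5 lists the 3 pair medians were above 0: 0.12, 0.05 and 0.06 for receptors, 0.13, 0.07 and 0.16 for granule genes, 0.07, 0.09 and 0.02 for the cytoskeleton and 0.15, 0.25 and 0.04 for signalling. Among random lists matched on expression, the medians stood at percentiles 87.3 (receptors), 95.4 (granules), 24.7 (transcription factors), 99.6 (cytoskeleton) and 99.9 (signalling). Random lists draw unrelated genes, while genes of the same list may move together, so such percentiles, here and below, are not p-values. Calls appeared without WT 2 for receptors (median 0.23, adjusted p = 0.0430) and granule genes (0.18, adjusted p = 0.0176), and without KO 3 for signalling (0.18, adjusted p = 0.0107). With the block and quantile normalization, the cytoskeleton (adjusted p = 0.0257) and signalling lists passed; signalling also passed on ranks of the moderated statistic, and granule genes with the block without pair 2. The median of all genes was itself 0.06 and scaling moved it, to 0.22 with libraries rescaled to a common sum. No member of these lists passed, over all genes or adjusted over the list alone. The receptor gene Pear1 was 4.78 ± 0.15 FPKM in WT and 6.50 ± 0.68 in KO, the angiogenic factor gene Vegfa 28.4 ± 4.54 and 41.5 ± 2.61, and the adhesive granule protein gene Thbs1 381 ± 47.7 and 552 ± 181 (SD, n = 3 each). Gp1ba, a receptor for von Willebrand factor, was 2.93 ± 1.06 and 4.48 ± 3.00, and the cytoskeletal severing protein gene Gsn 53.3 ± 16.8 and 72.3 ± 26.0.

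Of the 34 lists, 13 passed camera at the preset correlation, 4 higher and 9 lower relative to other genes, and the same 13 passed with the block. With an estimated correlation 0 passed camera, and the smallest adjusted p was 0.684 (0.657 with the block). With its correlation estimated, camera rests on the few residual degrees of freedom that 6 libraries leave, fewer still with the block. It could then call only very large shifts. Calls lost at an estimated correlation, here and below, are therefore not evidence that a list is unchanged. Fry called 0 lists as moving one way; for change in either direction it called 0, and 3 with the block, namely p53 targets (adjusted p = 0.0187), cytosolic ribosomal proteins (0.0389) and alpha-arrestins (0.0457). In 6 of the 13 called lists the medians of the 3 pairs had 1 sign, and in 7 they did not; in 7 of the 21 lists not called they were all above 0. Among random lists matched on expression, the interferon, immediate early and monocyte medians stood at percentile 100 and the alpha-arrestins at 95.9. Of the lists called lower, the proteasome median stood at percentile 47.1 and S phase at 4.76, neutrophil markers at 1.5, mast cell markers at 0.66, erythroid markers at 0.02, cytosolic ribosomal proteins at 0.01 and the other 3 at 0. Median, mean and test differed in sign for 8 lists, of which 0 were called.

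Interferon-induced genes had higher values in the knockout. Of 28 measured, 27 were higher and 1 lower, with a median change of 0.41 (camera, adjusted p = 5.02e-12; adjusted p = 0.684 with an estimated correlation) and pair medians of 0.63, 0.58 and 0.18. The ubiquitin-like modifier gene Isg15 was 2.62 ± 1.02 FPKM in WT and 6.71 ± 2.76 in KO, the transcription factor gene Irf7 3.42 ± 0.49 and 6.83 ± 1.70, and Ifit1 0.58 ± 0.47 and 2.10 ± 0.88 (SD, n = 3 each). No member passed over all genes; adjusted over the list alone 0 passed, and 10 with the block. Immediate early genes, which respond within minutes to stimulation, were higher in 21 of 21 (median 0.33; camera, adjusted p = 3.97e-05; adjusted p = 0.684 with an estimated correlation), with pair medians of 0.59, 0.14 and 0.12. This list was set as one of sample quality. Among its members Ier5 was 13.1 ± 0.75 FPKM in WT and 21.1 ± 5.88 in KO. The immediate early call was lost without WT 3 (median 0.18) and KO 1 (median −0.02), and with the block without pair 1. The median was 0.50 without WT 1 and 0.61 without KO 3. With array weights, whose estimation did not converge, both calls were lost. The type I interferon response then had a median of 0.188 (camera, adjusted p = 0.0581) and the immediate early genes 0.0949 (adjusted p = 0.688).

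Alpha-arrestins, the family of Txnip, and the glucose-sensing Mondo factors with their partners were higher in 9 of 10 measured genes (median 0.19; camera, adjusted p = 0.0161; adjusted p = 0.684 with an estimated correlation). Arrdc4, a paralog of Txnip that is likewise a target of Mondo factors, was at 7.06, 14.4 and 5.64 FPKM in WT 1 to WT 3 and at 12.7, 25.7 and 11.4 in KO 1 to KO 3, a difference of 0.82. Arrdc2 was 2.65 ± 0.28 FPKM in WT and 4.31 ± 0.74 in KO (SD, n = 3 each). Neither passed over all genes; adjusted over the list alone 0 members passed, and 1, Arrdc4, with the block. Of the fits with a library left out, the call for the list held only without WT 2 (median 0.16). It was lost without WT 1 (0.21), WT 3 (0.15), KO 1 (0.11), KO 2 (0.29) or KO 3 (0.15), with array weights (0.27) and with quantile normalization (0.14, camera, adjusted p = 0.0592). With quantile normalization and the block it was kept.

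Markers of monocytes, macrophages and dendritic cells were higher in 29 of 32 (median 0.41; camera, adjusted p = 3.97e-05; adjusted p = 0.684 with an estimated correlation), but the pair medians were 0.90, 0.21 and −0.05. H2-Ab1, an MHC class II chain, was 102 ± 12 FPKM in WT and 171 ± 76.3 in KO, and C1qa, a complement component made by macrophages, 4.08 ± 5.31 and 7.23 ± 2.02 (SD, n = 3 each). The call was lost without WT 1 (median 0.34) or KO 1 (0.08) and with array weights (0.03), and the median was 0.21 without WT 2 and 0.24 without KO 3. Markers of mast cells and basophils were lower in 10 of 17 (median −0.12; camera, adjusted p = 0.00777; adjusted p = 0.751 with an estimated correlation), with pair medians of 0.08, 0.07 and −0.48. Cpa3 was 287 ± 115 FPKM in WT and 185 ± 70.2 in KO, and Ms4a2, the IgE receptor beta chain, 48.3 ± 9.15 and 33.9 ± 13.6 (SD, n = 3 each); the small GTPase gene Rab44 went the other way, at 57.9 ± 6.06 and 81.8 ± 13.2. Adjusted over the list alone 0 of these passed, and 4 with the block: Cpa3, Fcer1a, Ms4a2 and Rab44. The call was lost without WT 1 (median 0.08), and without KO 3 the median was 0.25 (adjusted p = 0.497); it was −0.28 without WT 2, −0.33 without WT 3 and −0.56 without KO 1.

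Neutrophil and granulocyte markers were lower in 17 of 26 (median −0.10; camera, adjusted p = 0.00019; adjusted p = 0.684 with an estimated correlation), with pair medians of −0.33, −0.40 and 0.18. The eosinophil granule gene Prg2 was 533 ± 149 FPKM in WT and 374 ± 184 in KO, and the calcium-binding S100a8 1454 ± 289 and 995 ± 659 (SD, n = 3 each). The call was lost without WT 3 (median −0.03), KO 1 (−0.08) or KO 2 (0.04) and with array weights (0.15), while the median was −0.23 without WT 1, −0.17 without WT 2 and −0.47 without KO 3. Erythroid markers were lower in 11 of 19 (median −0.13; camera, adjusted p = 0.0229; adjusted p = 0.684 with an estimated correlation), with pair medians of 0.09, −0.01 and −0.19. The haemoglobin gene Hba-a1 was 7.81 ± 3.91 FPKM in WT and 2.19 ± 1.40 in KO, a value that depends on reads shared with its copy Hba-a2. It was the 1 member that passed adjusted over the list alone with the block, against 0 without. The call was lost without WT 2 (median 0.10), KO 1 (−0.03) or KO 3 (0.06) and on ranks of the moderated statistic; the median was −0.09 without WT 3 and −0.24 without KO 2. With libraries rescaled to a common sum, the medians of the mast cell, neutrophil and erythroid lists turned to 0.05, 0.07 and 0.02, against 0.22 for all genes. With quantile normalization the mast cell (camera, adjusted p = 0.0767) and neutrophil (0.0508) calls were lost, but with quantile normalization and the block both were kept.

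Core histone genes were lower in 60 of 64 measured (median −0.29; camera, adjusted p = 2.91e-20; adjusted p = 0.684 with an estimated correlation), with pair medians of −0.20, −0.56 and −0.05. Hist2h2ac was 691 ± 187 FPKM in WT and 410 ± 102 in KO, and Hist1h4a 1219 ± 326 and 786 ± 63.2 (SD, n = 3 each). The histone median was −0.17 without WT 2 and −0.43 without WT 3, both past the threshold, and −0.085 with quantile normalization. Many histone and ribosomal protein genes have near-identical copies or pseudogenes, so their single values are uncertain. Cytosolic ribosomal protein genes were lower in 74 of 81 (median −0.23; camera, adjusted p = 5.02e-12; adjusted p = 0.707 with an estimated correlation), with pair medians of −0.27, −0.15 and −0.27. Rps3a1 was 3949 ± 1932 FPKM in WT and 2186 ± 987 in KO, and Rpl26 169 ± 39.2 and 95.5 ± 45.4 (SD, n = 3 each). This call was lost without WT 2 (median 0.03), without KO 1 (median 0.05) and with quantile normalization (median −0.02, camera, adjusted p = 0.347). The median was −0.48 without WT 1 and −0.53 without KO 2. With the block the ribosomal protein call was kept without pair 1, 2 or 3. Rescaled to a common sum, the medians were −0.05 for ribosomal proteins and −0.11 for histones, against 0.22 for all genes, and both calls held. Adjusted over the list alone 0 histone and 0 ribosomal protein genes passed; with the block 1 of each did, Hist2h2ac and Rps3a1. Both lie on chromosome 3 within 200 tested genes of Txnip and belong to the group of genes taken up below.

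Nuclear-encoded genes of oxidative phosphorylation were lower in 67 of 78 (median −0.18; camera, adjusted p = 4.68e-13; adjusted p = 0.684 with an estimated correlation), with pair medians of −0.28, −0.02 and −0.20; the call was lost without KO 1 (median −0.02), and the median was −0.06 without WT 2, −0.29 without WT 1 and −0.32 without KO 2. With the block the oxidative phosphorylation call was kept without pair 1, 2 or 3. The complex I subunit gene Ndufa11 was 13.6 ± 0.99 FPKM in WT and 9.91 ± 1.11 in KO (SD, n = 3 each). Mitochondrial ribosomal protein genes were lower in 55 of 76 (median −0.11; camera, adjusted p = 3.09e-06; adjusted p = 0.684 with an estimated correlation), Mrpl41 being 14.4 ± 1.38 and 10.0 ± 1.06 FPKM. Proteasome genes were lower in 27 of 38 (median −0.05; camera, adjusted p = 0.00777; adjusted p = 0.684 with an estimated correlation), Psma4 being 229 ± 70.0 and 171 ± 42.6 FPKM. S phase genes were lower in 27 of 44 (median −0.03; camera, adjusted p = 0.009; adjusted p = 0.751 with an estimated correlation), the replication clamp gene Pcna being 355 ± 26.2 and 296 ± 33.2 FPKM. The mitochondrial ribosomal protein call was lost without WT 3 (median −0.01) and KO 1 (0.06), and its median was −0.17 without WT 1 and −0.19 without KO 2. The proteasome call was lost without WT 3 (−0.01) and KO 1 (0.05), and its median was −0.10 without WT 2, KO 2 or KO 3. The S phase call held only without WT 2 (−0.18) and KO 3 (−0.10) and was lost without WT 1 (0.06), WT 3 (0.05), KO 1 (0.01) or KO 2 (−0.03). Pair medians of the mitochondrial ribosomal protein, proteasome and S phase lists were 0.13, 0.11 and 0.17 in pair 2 and below 0 in pairs 1 and 3. Rescaled to a common sum, the oxidative phosphorylation median was −0.00655 and its call held (camera, adjusted p = 1.79e-11). Medians of the mitochondrial ribosomal protein, proteasome and S phase lists were then 0.07, 0.13 and 0.14, against 0.22 for all genes. The proteasome and S phase calls were lost (adjusted p = 0.0960 each). Both were lost with array weights and with quantile normalization too (adjusted p = 0.782 and 0.0786 with the latter), and the proteasome median was ordinary for genes of its expression.

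**Figure D3:**
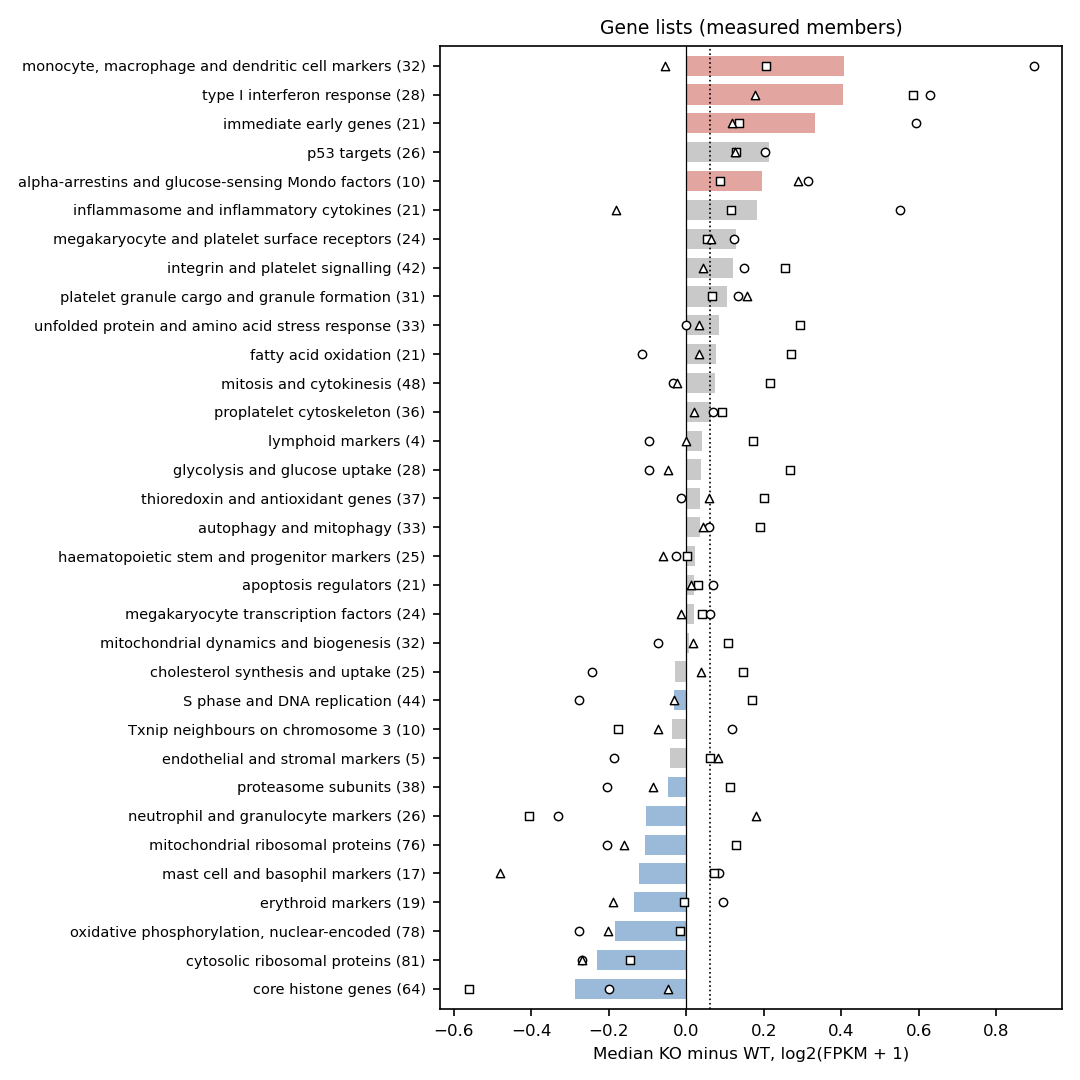
Median difference between KO and WT in log2(FPKM + 1) for 33 gene lists, sex-linked genes left out, with the number of measured members; bars give the median over all libraries and open symbols the medians of the 3 pairs (circle, square and triangle for pairs 1, 2 and 3). Red and blue bars passed camera at the preset correlation as higher and lower than other genes, grey bars did not, and the dotted line marks the median of all genes at 0.06. Symbols of the interferon list all lie above 0 and those of the monocyte list spread from −0.05 to 0.90.

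The remaining lists did not pass in the main test. Thioredoxin, which Txnip binds, and antioxidant genes had a median of 0.04 (camera, adjusted p = 0.991), with the haem oxygenase gene Hmox1 at 34.5 ± 17.2 FPKM in WT and 48.9 ± 17.3 in KO (SD, n = 3 each). Glycolysis and glucose uptake genes had a median of 0.04 (adjusted p = 0.804), and fatty acid oxidation genes 0.08 (adjusted p = 0.759). Inflammasome and cytokine genes had a median of 0.18 (adjusted p = 0.179), the pore-forming gasdermin gene Gsdmd being 26.1 ± 3.99 and 36.7 ± 5.57 FPKM. For p53 targets the median was 0.21 (adjusted p = 0.250), for apoptosis regulators 0.02 (0.922), for the unfolded protein and amino acid stress response 0.08 (0.782) and for autophagy and mitophagy 0.03 (0.804). Mitosis genes had a median of 0.08 (0.923), cholesterol genes −0.03 (0.0842), mitochondrial dynamics genes 0.01 (0.782), stem and progenitor markers 0.02 (0.686), lymphoid markers 0.04 (0.782) and endothelial and stromal markers −0.04 (0.923). The 10 measured neighbours of Txnip had a median of −0.04 (0.226) and the sex-linked genes −0.18 (0.686). Some of these lists passed elsewhere. Inflammasome and cytokine genes did in 6 alternatives, among them without WT 2 (median 0.26, adjusted p = 0.0312) and without KO 3 (0.48, adjusted p = 0.000191), and p53 targets without WT 2 (0.24, adjusted p = 0.00161) or KO 3 (0.27, adjusted p = 0.0459). Cholesterol genes were called lower in 7, among them median-ratio scaling (−0.10, adjusted p = 0.0474), without WT 2 (−0.25) and without KO 3 (−0.09). Left-out libraries also gave calls for fatty acid oxidation without WT 2 (0.13) or KO 1 (higher, 0.20) and KO 2 (lower, −0.12), for glycolysis without KO 1 (0.20) and KO 2 (−0.13), for autophagy without WT 2 (0.10), for the unfolded protein response without KO 1 (0.11) and for sex-linked genes without WT 3 (−1.73). Without WT 3, KO 3 is the only library left that lacks Y-linked transcripts, so the sex-linked call follows from unequal sexes in the groups. In none of the lists of this paragraph did a member pass, over all genes or adjusted over the list alone.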

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

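Combinations with the replicate block, and the scaling without Rpph1 and Rmrp, were chosen after seeing the data; the other alternatives were planned. Txnip passed in 22 of 22 alternatives, between −10.43 and −6.98 on the log2 scale, the lower value with a pseudocount of 0.1. Cd1d2 passed in 17 of 21, with adjusted p between 1.07e-21 and 0.1, Mnd1 in 7 of 22 and Arrdc4 in 3 of 22. Over 143 named genes, 3116 values under alternatives gave 92 newly past the threshold, 4 no longer past it and 0 reversed.

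The count of genes higher in KO (1) was 0 with no filter and 0 with a mean of at least 5 FPKM, where Cd1d2 is not tested. It was 2 with the replicate block, alone or with quantile normalization or median-ratio scaling, and 519 with array weights; genes lower in KO (1) were then 320. The estimation of array weights stopped before it converged. With the block and without pair 1, 2 or 3, genes higher in KO were 9, 94 and 68 and genes lower 27, 48 and 50; these fits keep 1 residual degree of freedom. With a library left out, genes higher ranged from 0 (WT 2, WT 3 or KO 3) to 1, and genes lower from 1 to 2, the second gene, Gm7367, appearing without KO 1. Leaving out 1 library also unbalances the pairs and the share of each sex between the groups.

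Gene lists called (13) were 7 with quantile normalization, and 15 with quantile normalization and the block, 10 of these shared with the main test. They were 6 with array weights (type I interferon response: median 0.188, camera, adjusted p = 0.0581), 0 with an estimated correlation, with or without the replicate block, and 0 with fry. With the block and without pair 1, 2 or 3 they were 7, 16 and 9. Without pair 1 the monocyte, immediate early, alpha-arrestin, mitochondrial ribosomal protein, proteasome and S phase calls were lost. Without pair 2 the neutrophil call was lost, and without pair 3 the erythroid, mast cell, alpha-arrestin, S phase and proteasome calls. The interferon, histone, cytosolic ribosomal protein and oxidative phosphorylation calls held without each of the pairs. With a library left out, between 6 (without KO 1) and 18 (without WT 2) lists were called, 8 without WT 3 and 9 without WT 1. The block changed the call of 0 lists and of no named gene other than Mnd1. Of 882 list values under alternatives, 751 kept direction and call, 92 were no longer past the threshold, 30 were newly past it and 9 reversed. With array weights the neutrophil median was 0.152 and the monocyte list ranked lower than other genes (median 0.0269); with the block without pair 1 the S phase median was 0.0974. The other reversals came without KO 1, KO 2 or KO 3: over the left-out libraries, medians ran from −0.128 to 0.202 for glycolysis, −0.0246 to 0.606 for immediate early genes, −0.186 to 0.0563 for mitochondrial ribosomal proteins, −0.104 to 0.0490 for proteasome subunits, −0.124 to 0.203 for fatty acid oxidation and −0.563 to 0.249 for mast cell and basophil markers. The interferon and histone calls held whichever library was left out, with medians from 0.289 to 0.553 and −0.4253 to −0.1705; neutrophil medians ran from −0.474 to 0.0424. Except where named, the cause was not tested. Rescaling moved the median of all genes from 0.06 to 0.22 (0.17 without Rpph1 and Rmrp), and list directions relative to it kept their sign for the 13 called lists under all 4 scalings. All but quantile normalization multiply each library by a common factor, so they can hardly move a list relative to all genes. With quantile normalization the cytosolic ribosomal protein median relative to all genes went from −0.29 to −0.0239. Depth could not be used to set detection limits, as it was only estimated and stays unknown for KO 2.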

Other observations

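The tests of gene order around Txnip, of Cd1d1, of the most abundant monocyte markers and of scaling were chosen only after the results were seen; those of the first pair, of transcript length and of other splits were set before. Several of the genes with the smallest p lie on chromosome 3, which also carries Txnip. With the block, 9 of the 50 genes of smallest p, Txnip left out, stood within 200 tested genes of it. That region holds 400 tested genes, against 539 on the whole chromosome, so it is not a close neighbourhood of Txnip. The 9 genes were Mnd1, Cd1d2 and Gm4349, higher in the knockout, and Sh3d19, Rps3a1, Tsacc, Them4, Anxa9 and Hist2h2ac, lower, each in 3 of 3 pairs. Tsacc, which encodes a chaperone-associated protein, was 3.85 ± 0.74 FPKM in WT and 1.62 ± 1.24 in KO, and Gm4349, a predicted gene, 0.55 ± 0.27 and 2.64 ± 1.18 (SD, n = 3 each). Both were named after their values were seen, and of the 9 genes Cd1d2 and Mnd1 passed the threshold with the block.

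A candidate explanation for the chromosome 3 genes is DNA of another genetic background that stayed linked to the targeted allele, although the labels give C57BL/6 for both genotypes. The 9 genes exceed the 1.78 expected from the size of the region and the 7 of the next highest region of as many genes, on chromosome 11; among the 10 genes of smallest p the counts were 5 and 2, but among the first 100 they were 9 and 11; without the block they were 6 and 1 among 10, and 12 and 10 among 100. An effect of the allele on its nearest genes alone is argued against, since all 9 lie outside the fixed list of nearest neighbours, at positions −157 to −11 from Txnip in the order of tested genes, and so on the same side. Why none lay on the other side was not tested, for linked DNA or otherwise. Reads moved to Cd1d2 out of an unchanged Cd1d1 signal are argued against, since Cd1d1 was itself higher, by 4.46 FPKM and in 3 of 3 pairs. If the Cd1d1 signal rose, part of its reads could still have been counted as Cd1d2, which this test cannot tell. An effect of Txnip loss on these genes stays open, and sequence variants were not looked at.

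The higher monocyte, macrophage and dendritic cell markers rest on the first pair: without it, in the fit with the block, their median was 0.0802 (camera, adjusted p = 0.849), though it also fell to 0.209 without WT 2 and 0.237 without KO 3. Mature lineages were depleted before culture and CD41+ cells sorted after it, steps meant to leave such cells out. A larger share of them among those sorted cannot be told apart from a change within cells. Of the 10 most abundant markers 8 had a higher mean of log2(FPKM + 1), Apoe by only 0.0098, but Lyz2, Ctss and Apoe were lower in 2 of 3 pairs. The largest rises were those of H2-Eb1 (0.72), H2-Ab1 (0.64), Cd74 (0.53) and H2-Aa (0.44), while Ly6c2 (−0.03) and Ccr2 (−0.10) were lower. The interferon genes do not rest on the first pair, their median being 0.317 without it (camera, adjusted p = 7.48e-05). No test here separates an effect of genotype on these lists from a difference between mice or cultures that the labels do not describe. Both calls were lost with an estimated correlation, where the test has little power.

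Histone, ribosomal protein and oxidative phosphorylation genes have short transcripts, and across genes the change between KO and WT rose with transcript length (Spearman 0.207, and 0.164, 0.0367 and 0.225 in pairs 1 to 3; between libraries of 1 genotype it ran from −0.248 to 0.306; genes are not independent). Against 10000 random lists matched on length and expression, the share with a median as low was 0% for histones, 0% for mitochondrial ribosomal proteins, 0.16% for cytosolic ribosomal proteins and 1.04% for oxidative phosphorylation. Matched lists had medians of −0.147, 0.002, −0.151 and −0.112 themselves. The random lists draw unrelated genes, while genes of the same list may move together, so these shares cannot argue against length. For cytosolic ribosomal proteins the match on expression is also coarse, as 58 of the 81 are among the 100 most abundant genes. Scaling as the whole cause is argued against for mitochondrial ribosomal proteins, whose median with the block and quantile normalization was −0.126 and past the threshold at the preset correlation; the main calls of all 4 lists were lost at an estimated one. For oxidative phosphorylation (−0.104), histones (−0.0850) and cytosolic ribosomal proteins (−0.0162) scaling and a change of these genes cannot be told apart: relative to all genes the first went from −0.245 to −0.112 and histones from −0.347 to −0.0927, both still past the threshold, and 58 of the 81 ribosomal protein genes are among the 100 most abundant, which quantile normalization largely equalises. An effect of genotype stays untested beside these.

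The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2 genes and the highest other split 2, so that 2 of the 10 splits reached that count. It called 13 lists against 17 for the highest other, and 5 of the 10 splits reached 13; the split with 17 set WT 1, WT 2 and KO 1 against the rest. The real split sets the members of all 3 pairs apart; 3 other splits do so too, and with the block they called 3, 0 and 0 genes against 3, and 7, 11 and 10 lists against 13. The remaining 6 splits part 1 pair each.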
